A study of Mus musculus with 2 samples.

How the data were processed

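Total RNA from 2 samples of mouse bile duct organoids, 1 per group, was compared. Per the labels' protocols, tissue was dissociated and grown in Matrigel with EGF, R-spondin, Noggin, FGF10 and Wnt3a-conditioned medium, organoids were infected with a Cre or a control lentivirus, and RNA was extracted with TRIzol, amplified and labelled with Cy3 using a low-input kit. Each sample was hybridised to 1 single-colour Agilent mouse array of design 028005, and per the file headers both arrays share a slide and a scan, so that neither slide nor scan separates the groups.

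The deposited scanner tables hold the linear intensity of each of 62976 spots as written by Agilent Feature Extraction, version 10.7.1.1 per the file headers and 9.5.1.1 per the submitters' processing notes. The difference between these versions was not resolved. Per the file headers, the processed signal intensity is corrected by spatial and multiplicative detrending within each array, with no normalization between arrays, and each spot carries a modelled error and flags for being well above background, saturated or an outlier. Probe coordinates are on mm9. A deposited table of values per probe holds linear intensity with no statement of how it was made. Its columns hold nearly the same set of values in another order, with medians of 12.4 and 12.4 and sorted values that differ by at most 0.00279 of their size, as quantile normalization gives. On the log2 scale they correlate across probes with the scanner signal at 0.9995 and 0.9998. This table served as an alternative.

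For the main values, log2 of the processed signal was taken for 59305 non-control spots, log2 of the 75th percentile of the array was subtracted, and unflagged spots of a probe were averaged (132 and 125 spots carried an outlier flag). A gene is the mean over its probes that were well above background and unsaturated on both arrays. Probes were named through a RefSeq gene table of GRCm38.p6, used for names only: 27235 probes matched by transcript accession, 3581 by symbol and 565 by a unique synonym, and 24298 kept the name in the file. Genes without a match were left out of the main counts. Clca3b, Depp1, Acod1 and Ccn4 appear in the files under the older names Clca4, 8430408G22Rik, Irg1 and Wisp1.

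No test between groups was run, since 1 array per group leaves no residual degrees of freedom. Genes were counted as higher or lower at a difference of at least 2-fold. The error of a gene is that of the scanner error model, beside the SD over repeated spots and over probes. A gene well above background on 1 array only is given as a bound, the brighter level against the higher of the dim probe's own level and the lowest level well above background on the dim array. For each gene list, the median over members measured on both arrays was set against 10000 random lists of the same size matched on mean expression in 20 bins, a description of these arrays and not a test of the conditions.

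The samples, the gene lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule names the 12 highest and the 12 lowest genes among those with a plain symbol, probes that share a direction and a level on the brighter array at or above the median of detected genes; the 5 largest bounds in each direction; every probe of Tgfbr2 and Cdh1; and in each list the 2 most positive and 2 most negative members. Not every gene or list that was fixed in this way is reported here. Members named outside it, such as Il33, Il1a, Ptgs2, Itga5, Hey1 and members measured on 1 array, were chosen after their values were seen.

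The steps were tested on simulated arrays with 200 changed among 12225 genes. Both simulated arrays were given the same scaled probe levels, the mean of the real arrays. Each kept the scanner errors, with large ones capped, the background flags and the brightness of its real array. Of 50 genes changed 8-fold and 50 changed 4-fold, 100% were called in the right direction, against 52.0% of 50 changed 2-fold and 2.00% of 50 changed 1.5-fold. Of 12025 unchanged genes 3 were called. Spread between cultures is not part of this simulation, nor is a difference between the arrays that changes with brightness. The count of unchanged genes called does not cover either source.

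The other settings were normexp background correction (offset 50) of mean and local background intensity, quantile normalization, centring on the median of measured probes, the deposited value table, the brightest probe of a gene, no filter and a stricter filter on dim probes, and thresholds of 1.5-fold and 3-fold. Loess on intensity (span 0.3), scaling to the spike-in transcripts and leaving Tff1 out of its list were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and R 4.3.3 with limma 3.58.1, were used. Probe sequences were not mapped to a genome, and which exons the probes lie in was not analysed here.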

Results

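Gene expression was measured in organoids grown from the extrahepatic bile duct of KTC mice on the C57BL/6J background, after infection with a lentivirus. One organoid sample received a control lentivirus and is called Cre-negative, and the other received a lentivirus expressing Cre recombinase and is called Cre-positive. Infected cells were selected with puromycin, and RNA was taken 2 weeks after infection. Each group held 1 sample on 1 single-colour Agilent array, and both arrays lay on the same slide and were scanned together. The labels do not spell out KTC. From the published mouse model it is taken here as carrying, among its alleles, loxP-flanked Tgfbr2 and Cdh1. The comparison asks how expression differs after Cre, which is meant to recombine these alleles, was delivered in culture. With 1 array per group no test between groups can be made, no difference below has a replicate check, and the number of arrays limits the precision. Spot and probe errors are technical errors within the arrays. A level is the log2 signal of a probe minus log2 of the 75th percentile of its array, and a difference is the level in Cre-positive minus that in Cre-negative.

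Of 55681 probes, 23384 (42.0%) were well above background on the Cre-negative array and 25984 (46.7%) on the Cre-positive array, and 0 spots were saturated on either. The 75th percentile of signal was 164 and 345 on the 2 arrays. Over 219 probes printed in 10 spots each, the SD of the log2 difference between spots was 0.06 at the median and 0.18 at the 90th percentile. Across 3411 genes with several measured probes, the SD between probes was 0.21 at the median, and the scanner error model gave a median error of 0.21 per gene. The correlation of the 2 arrays across 12225 genes was 0.945, and genes are not independent replicates.

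These genes of the KTC model were read first, as a check of the labels. Cdh1, which encodes E-cadherin, the adhesion protein of epithelial adherens junctions, was 17.3-fold lower in Cre-positive (difference -4.11, scanner error 0.20, SD over 10 spots 0.06). Its level went from 5.34 to 1.22. Tgfbr2, the type II TGF-beta receptor, was not lower on either probe. Probe A_51_P450573 was 1.59-fold higher (0.67, error 0.20), or 0.36 on the log2 scale after quantile normalization, and probe A_55_P2107288 differed by 0.16 with an error of 0.22. In mm9 coordinates the Cdh1 probe lies at chromosome 8, 109193812 to 109193871, at position 4078 of its transcript. The Tgfbr2 probes lie at chromosome 9, 115997155 to 115997214 and 115999496 to 115999555, at transcript positions 4386 and 2045. The sources used here do not say which exons Cre removes, and a probe outside the removed part does not check a deletion.

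**Figure D1:**
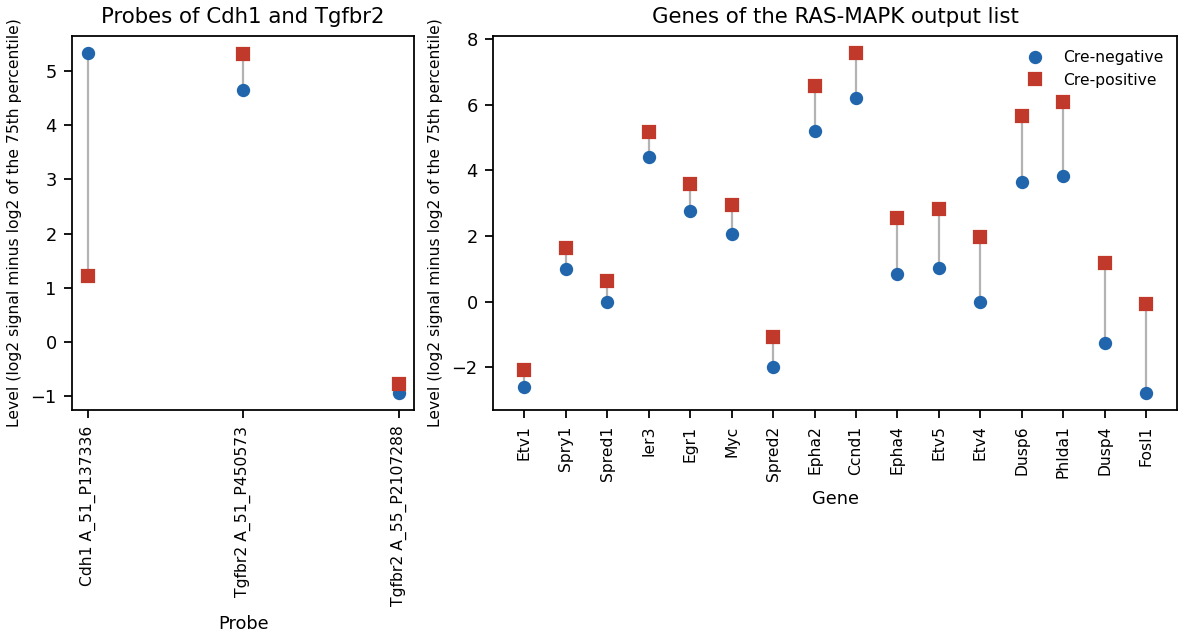
Levels (log2 signal minus log2 of the 75th percentile of the array) in the Cre-negative (circles) and Cre-positive (squares) organoid, 1 array each, for each probe of Cdh1 and Tgfbr2 on the left and for the 16 measured genes of the RAS-MAPK output list on the right. The Cdh1 probe went from 5.34 to 1.22, and all 16 genes on the right were higher in Cre-positive, by 0.54 to 2.70.

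Among the highest-ranked genes were a water channel and precursors of the cornified envelope, and among the lowest a matrix protein, haptoglobin and the enzymes that make itaconate and nitric oxide. Aqp5, a water channel of secretory epithelia, was 92.8-fold higher (6.54, error 0.23). Ivl (involucrin, 6.01) and Sprr1a (5.56), both precursors of the cornified envelope of squamous cells, were 64.7-fold and 47.1-fold higher. Tff1, a trefoil peptide of gastric mucous cells, was 41.3-fold higher (5.37) on 2 probes that share 55 bases and are not independent. The file places both on chromosome 5 and the gene table has Tff1 on chromosome 17, so which transcript they read is uncertain. In the other direction, Ltbp2, an extracellular matrix protein named latent TGF-beta binding protein 2, was 516-fold lower (-9.01, error 0.26), from a level of 5.73 to -3.28. Hp, the acute-phase protein haptoglobin, was 105-fold lower (-6.71), Acod1, the enzyme that makes itaconate, 93.7-fold lower (-6.55), and Pdpn, the membrane glycoprotein podoplanin, 91.5-fold lower (-6.52).

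The other 8 of the 12 highest genes were Gsta2 (5.34), Emp1 (5.29), Clca3b (5.20), Cyp2d34 (5.01), Ddn (4.66), Depp1 (4.65), Krt20 (4.58) and Phgr1 (4.33). Krt20 is a keratin of differentiated gastrointestinal epithelium. Gsta2 has near-identical neighbours in its family, so its single probe is uncertain as to which copy it read. The other 8 of the 12 lowest were Gpx3 (-6.21), Armcx2 (-5.21), Dram1 (-5.15), Cyfip2 (-5.02), Ncam1 (-4.99), Sparc (-4.94), Nos2 (-4.91) and Syt13 (-4.90). Gpx3 is the extracellular glutathione peroxidase, Sparc a matrix glycoprotein and Nos2 the inducible nitric oxide synthase. The lowest level well above background on the Cre-positive array was -4.23, and Ltbp2, Pdpn, Hp, Armcx2, Dram1, Cyfip2, Sparc and Syt13 lay within 1 log2 unit of it, so the size of their difference rests on a dim signal there. The same holds on the Cre-negative array, where the lowest such level was -3.22, for Ivl and, in the gene lists, for Fosl1, Areg, Slc10a2, Sox17, Bub1 and Eda2r, and on both arrays for Tnfrsf19, Notch1 and Cel. In mm9, the probe of Aqp5 lies at chromosome 15, 99425138 to 99425197, that of Ivl at chromosome 3, 92375367 to 92375426, that of Ltbp2 at chromosome 12, 86124167 to 86124226, and that of Hp at chromosome 8, 112099045 to 112099104.

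Genes that were well above background on 1 array and not on the other have only a bound. Prap1, a proline-rich acidic protein of epithelia, was at least 120-fold higher in Cre-positive, followed by Cyp2b10 (at least 66.9-fold), Tgm1 (65.6), Rhox5 (55.0) and Mcpt2 (42.3). Tgm1 is the transglutaminase that cross-links the cornified envelope. Saa3, an acute-phase serum amyloid, was at least 554-fold lower, from a level of 4.89 to a signal that was not well above background. Ccn4 (57.3), Sirpa (52.8), Tmeff2 (44.3) and Syce1 (35.9) followed.

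Of 12225 annotated genes measured on both arrays, 910 were at least 2-fold higher in Cre-positive and 912 at least 2-fold lower, and 10403 differed by less. At 4-fold the counts were 194 and 201, and at 8-fold 52 and 68. A further 242 genes measured on 1 array were at least 2-fold higher and 376 at least 2-fold lower by their bound. Of 307 genes with several probes and a mean difference of at least 2-fold, 305 had all probes in the same direction. These counts describe 2 arrays and come from no test. Lower calls gathered among dim genes, with 435 among the 2445 genes of lowest mean level and 48 among the 2445 of highest, and higher calls made up 49.9% of all calls here, 65.4% (759 against 402) when dim probes were filtered more strictly, 60.5% (806 against 526) after normexp background correction, 17.6% (1501 against 7039) with no filter, which lets in probes at background on both arrays (median difference -1.02 over 28722 probes, set by the scaling), and 99.1% (10336 against 99) on the scale of the spike-in transcripts, which adds 1.59 to every difference. Every difference given here is relative to the 75th percentile of its array: with 1.59 added, none of the 8 negative medians among 26 gene lists stays negative, while the standing of a list against other genes is the same.

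**Figure D2:**
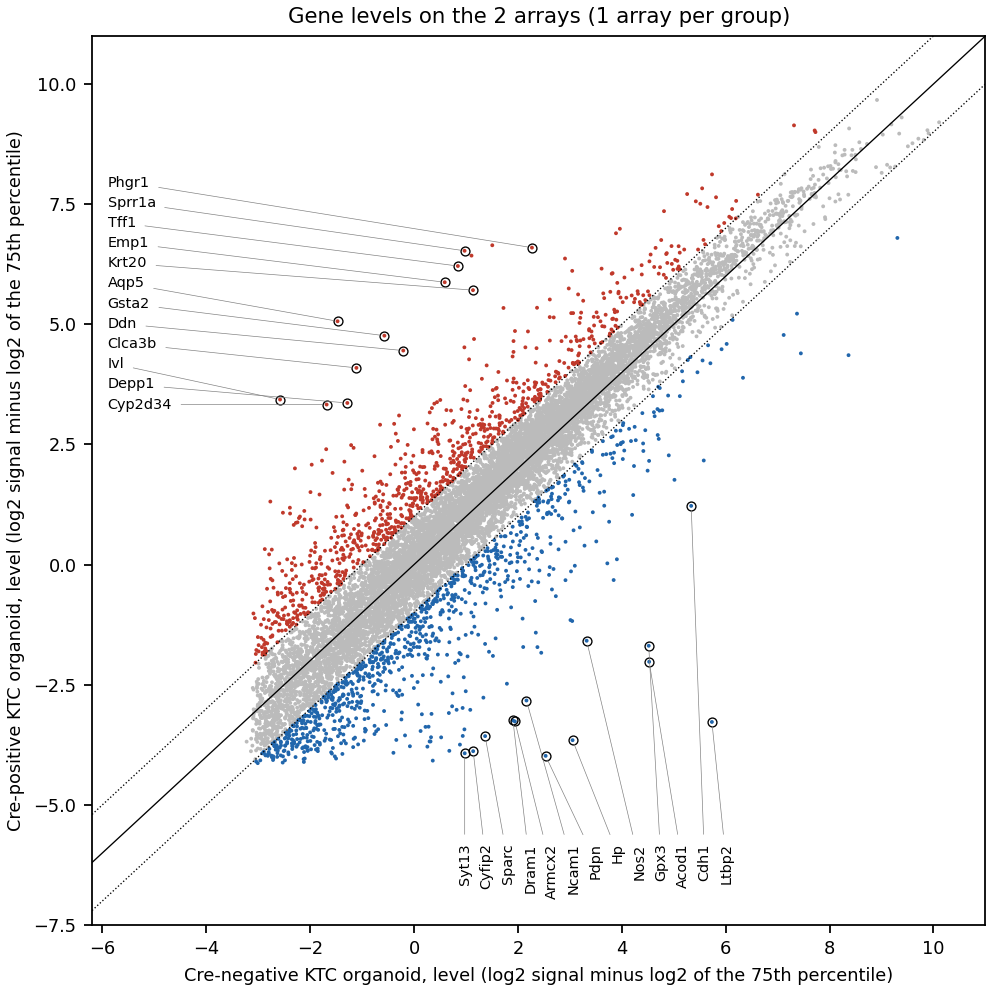
Level of each of 12225 annotated genes in the Cre-negative (horizontal axis) and Cre-positive organoid (vertical axis), as log2 signal minus log2 of the 75th percentile of the array, 1 array per group. The solid line marks equal levels and the dotted lines a 2-fold difference; the 910 genes at least 2-fold higher are red, the 912 lower are blue, and the 24 genes named by rank and Cdh1 are circled and named.

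Genes of the RAS-MAPK output and EGF receptor ligand lists were mostly higher in the Cre-positive organoid. Of the RAS-MAPK output list, transcripts that follow ERK activity, 16 of 20 genes were measured on both arrays and all 16 were higher, 9 of them at least 2-fold. The median difference was 1.36, above all 10000 random lists matched on mean expression (percentile 100). Fosl1, an AP-1 subunit, was 6.51-fold higher (2.70) and Dusp4, a MAP kinase phosphatase, 5.50-fold higher (2.46). Dusp5 and Spry2 were well above background only on the Cre-positive array, at least 3.93-fold and 2.17-fold higher. Of the EGF receptor ligands, 4 of 6 measured genes were at least 2-fold higher, with a median of 1.64 (percentile 100). Areg (amphiregulin) was 19.6-fold higher (4.30) and Ereg (epiregulin) 4.30-fold higher (2.10), while Nrg1, which binds other receptors of that family, differed by -0.18 with an error of 0.20.

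The genes of the DNA replication and mitosis lists that were measured on both arrays all had positive differences. Of 16 measured DNA replication and S phase genes, 10 were at least 2-fold higher and 0 lower (median 1.26, percentile 100). Rrm2, a subunit of ribonucleotide reductase, led at 2.73, followed by Tk1 (thymidine kinase) at 1.90. Of 17 measured mitosis genes, 15 were at least 2-fold higher and 0 lower (median 1.86, percentile 100). Plk1 and Bub1, kinases of mitosis and its checkpoint, stood at 2.26 and 2.22. Of 19 p53 target genes, 2 were at least 2-fold higher, Eda2r (1.08) and Btg2 (1.01), and 0 were lower. The 2 probes of Eda2r are dim and differ in direction (SD between probes 1.67), so it is uncertain. Sesn1 (-0.42) and Bbc3 (-0.31) had the most negative differences of that list, whose median of 0.41 lay at percentile 95.1 and was 0.15 after quantile normalization.

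TGF-beta target genes split by direction. Of 16 measured, 6 were at least 2-fold lower and 1 was at least 2-fold higher. The median was -0.25 (percentile 0.44) and the mean, pulled by Ltbp2, was -0.94. Under the stricter filter on dim probes the median was -0.026. Ltbp2 (-9.01) and Pmepa1 (-2.63, 2 probes), an inhibitor of TGF-beta signalling, were the lowest. Thbs1 (thrombospondin 1) was the highest at 1.22. Of the mesenchymal and EMT list only 7 of 16 genes were measured on both arrays, 5 of them at least 2-fold lower and 1 higher. The median was -1.57 (percentile 0.02), or -3.02 under the stricter filter and -1.13 after normexp background correction. Sparc (-4.94) and Fn1, which encodes fibronectin (-3.05), were the lowest. S100a4, a calcium-binding protein linked to cell motility, went the other way at 3.50 over 2 probes, and Tagln, chosen after its value was seen, differed by -0.13. Itga5, the alpha subunit of the fibronectin receptor, was at least 9.72-fold lower. Snai2 was well above background only on the Cre-positive array (level -3.93), with no bound. Beside this group, 10 of 12 fibroblast markers were at background on both arrays. Col6a1, measured on the Cre-negative array only, was at least 19.7-fold lower, while Fbln1 was well above background only on the Cre-positive array (level -4.11), with no bound.

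Most measured genes of the 2 junction lists lay within 2-fold. Of 18 adherens junction and desmosome genes, a list that leaves out Cdh1 (-4.11), 15 lay within 2-fold, and the median was -0.22 (percentile 0.89). Cdh17, a cadherin of intestinal epithelium, was higher at 2.22. Ctnnd1, the catenin p120, was next at 0.69 on the mean of 2 probes and -0.048 on its brighter probe. Nectin4 (-1.16) and Pkp1 (plakophilin 1, -1.08) were lower. Of 15 tight junction genes, 14 lay within 2-fold (median 0.53, percentile 98.8, or 0.26 after quantile normalization), with Cldn6 at 1.43, Ocln at 0.96, Cldn8 at -0.92 and Cldn4 at -0.80. Of 16 matrix protease, laminin and integrin genes, 2 were at least 2-fold higher and 1 lower. Plat and Plaur, tissue plasminogen activator and the urokinase receptor, were higher at 3.21 and 1.90, while the laminin chains Lama3 and Lamb3 stood at -1.42 and -0.78. The median of that list was 0.25 (percentile 54.1) and was -0.00101 after quantile normalization.

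Of 16 biliary epithelial markers, 15 were measured on both arrays and 13 of them lay within 2-fold (median 0.27, percentile 51.0, or 0.017 after quantile normalization). Muc1 (1.47) and Krt19 (1.27) were higher, and Onecut1 (-0.84) and Sox4 (-0.54), transcription factors of the biliary lineage, had the most negative values. Of 12 bile duct transport genes, 5 were measured on both arrays, 4 of them at least 2-fold higher (median 1.57, percentile 99.96), and 5 were at background on both. Gpbar1, at least 1.63-fold higher, and Sctr, with no bound, were well above background only on the Cre-positive array. With no filter, where these 7 enter, the median was 0.0253. Slc10a2, the apical bile acid transporter, was 10.9-fold higher (3.45) and the water channel Aqp1 3.18-fold higher (1.67), while the anion exchanger Slc4a2 differed by -0.04. Stem and peribiliary gland markers had a median of 0.02 (9 measured, percentile 56.4). Sox17, a transcription factor of the biliary and endoderm lineage, was 8.84-fold higher (3.14), followed by Pdx1 (0.81), and the receptors Tnfrsf19 (-1.13) and Lrig1 (-0.33) were the lowest.

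Gastrointestinal mucous genes included some of the largest differences. Of 9 measured genes, 6 were at least 2-fold higher and 3 at least 2-fold lower (median 2.03, percentile 100, or 1.52 without Tff1, whose probes are uncertain). The median was 0.21 with no filter, where 8 genes at background on both arrays and 4 seen only on the Cre-positive array enter. Tff1 (5.37) and Tff3 (2.55), both trefoil peptides, were the highest, and Tff2 (-1.47), the trefoil peptide of gastric gland mucous cells, and Gkn3 (-1.44), a gastrokine, were the lowest. Gkn2, Anxa10 and Agr2, whose products belong to gastric and mucous cells, were well above background only on the Cre-positive array, at least 17.3-fold, 10.5-fold and 5.01-fold higher. The secreted mucins Muc5ac, Muc5b and Muc6 were among the 8 genes at background on both arrays. The remaining raised genes were Muc4 (2.37), Cdx2 (2.26), Vil1 (2.03) and Ctse (1.02), and the remaining lower gene was Spdef (-1.05), dim on both arrays.

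Cytokines and chemokines went both ways. Of 16 measured, 3 were at least 2-fold higher and 4 at least 2-fold lower (median -0.35, percentile 0.32, or -0.14 after normexp background correction). Csf2 (GM-CSF) was higher at 2.32 and the neutrophil chemokine Cxcl3 at 1.51. Ccl5, a T cell and monocyte chemokine, was 7.41-fold lower (-2.89) and Csf1 2.61-fold lower (-1.38, 3 probes). Il33, an alarmin of barrier epithelium singled out after its value was seen, was measured only on the Cre-positive array and was at least 29.7-fold higher, with Il1a (7.10) and Ptgs2 (5.30) in the same direction. Of 17 interferon-stimulated genes, 6 were at least 2-fold higher and 0 lower (median 0.73, percentile 100, or 1.39 under the stricter filter). Oas2 (3.48) and Ifit3 (2.82), antiviral effectors, led the list, and Ifit2 (-0.87) and Gbp2 (-0.67) were its lowest. Antigen presentation genes had a median of -0.22 (12 measured, percentile 0.27, or -0.43 after quantile normalization), with Cd74 at -1.15, H2-Q4 at -0.86, H2-T23 at 0.38 and Tap1 at 0.37.

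Genes of the Wnt, Notch and YAP pathways went both ways. Of 9 measured Wnt target genes, 2 were at least 2-fold lower, Znrf3 (-1.14) and Tnfrsf19 (-1.13), and 1 was higher, Rnf43 (1.15), followed by Sp5 (0.98). The median was -0.25 (percentile 33.4) and changed sign under the stricter filter (0.92) and under loess on intensity (0.15). All 8 measured Notch pathway genes lay within 2-fold (median -0.30, percentile 9.80). Jag1 and Notch1 stood at -0.95 each, Hes1 at 0.24 and Jag2 at 0.11, while Hey1 and Dll4, seen only on the Cre-negative array, were at least 5.36-fold and 5.79-fold lower and Nrarp, seen only on the Cre-positive array, at least 1.67-fold higher. Of 15 YAP target genes, 3 were at least 2-fold lower and 1 higher (median -0.09, percentile 4.35, or -0.33 after quantile normalization), with Axl at -1.90, Tgfb2 at -1.38, F3 at 1.23 and Ankrd1 at 0.97.

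Of 22 cholesterol synthesis genes, 16 were at least 2-fold higher and 1 at least 2-fold lower (median 1.26, percentile 100). Cyp51 (2.12) and Idi1 (2.05), enzymes of the sterol pathway, were highest, and Acat2, a thiolase, was the exception at -1.07. Of 16 NRF2 target genes, 7 were at least 2-fold higher and 0 lower (median 0.75, percentile 99.96). The probes of Aldh3a1, 1 of these 7 and named after its values were seen, differ in direction (SD 1.46). Gsta4 (2.21), a glutathione transferase, and Gclc (2.17), a subunit of an enzyme of glutathione synthesis, led, and Gstm1 had -0.31. Hmox1 (0.06), Txnrd1 (0.03) and Gclm (0.02), the other subunit of that enzyme, differed by less than their scanner errors. Nqo1 was at background on both arrays. Of 16 glycolysis genes, 13 lay within 2-fold (median 0.55, percentile 99.4). Pgk1 (1.67) and Pkm (1.31) were higher, and the lactate transporter Slc16a3 was 6.56-fold lower (-2.71, 2 probes), with Pfkl at -0.47. Endoplasmic reticulum stress genes had a median of 0.22 (15 measured, percentile 62.8), with Atf3 at 1.58, Sdf2l1 at 1.24, Xbp1 at -0.51 and Hyou1 at -0.20.

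Markers of other cell types were mostly at background. Of 12 haematopoietic markers, 6 were at background on both arrays and 5 were measured on both. Itgam (-1.54) and Csf1r (-1.51, 3 probes) were lower, while Cd68 (1.06) and Cd3e (0.48) were higher. The median of these 5 was 0.17 (percentile 51.3) and the mean -0.27, and the median was -0.20 after quantile normalization. Of 10 endothelial markers, Kdr alone was measured on both arrays (0.84). Of 13 hepatocyte markers 3 were measured on both arrays, Hnf4a (0.84), Apoa2 (0.41, or -0.27 on its brighter probe) and Ttr (0.14), with a median of 0.41 (percentile 80.4). That median was 0.080 after normexp background correction and 0.14 on the brightest probe of each gene. It was -1.02 with no filter, where 7 markers at background on both arrays and 3 seen only on the Cre-negative array enter. Tat and Serpina1a were well above background only on the Cre-negative array, at least 6.21-fold and 3.43-fold lower, as was Fgb with a larger bound. The pancreatic acinar markers Cel and Ctrb1 differed by -0.51 and -0.46 at dim levels, Cel by 0.16 under loess on intensity, and the enterocyte gene Fabp2 by -0.13. No other acinar, enterocyte or enteroendocrine marker was measured on both arrays. Lct, Sct and Cck, at least 1.62-fold, 1.49-fold and 1.32-fold higher, and Chga, with no bound, were well above background only on the Cre-positive array.

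**Figure D3:**
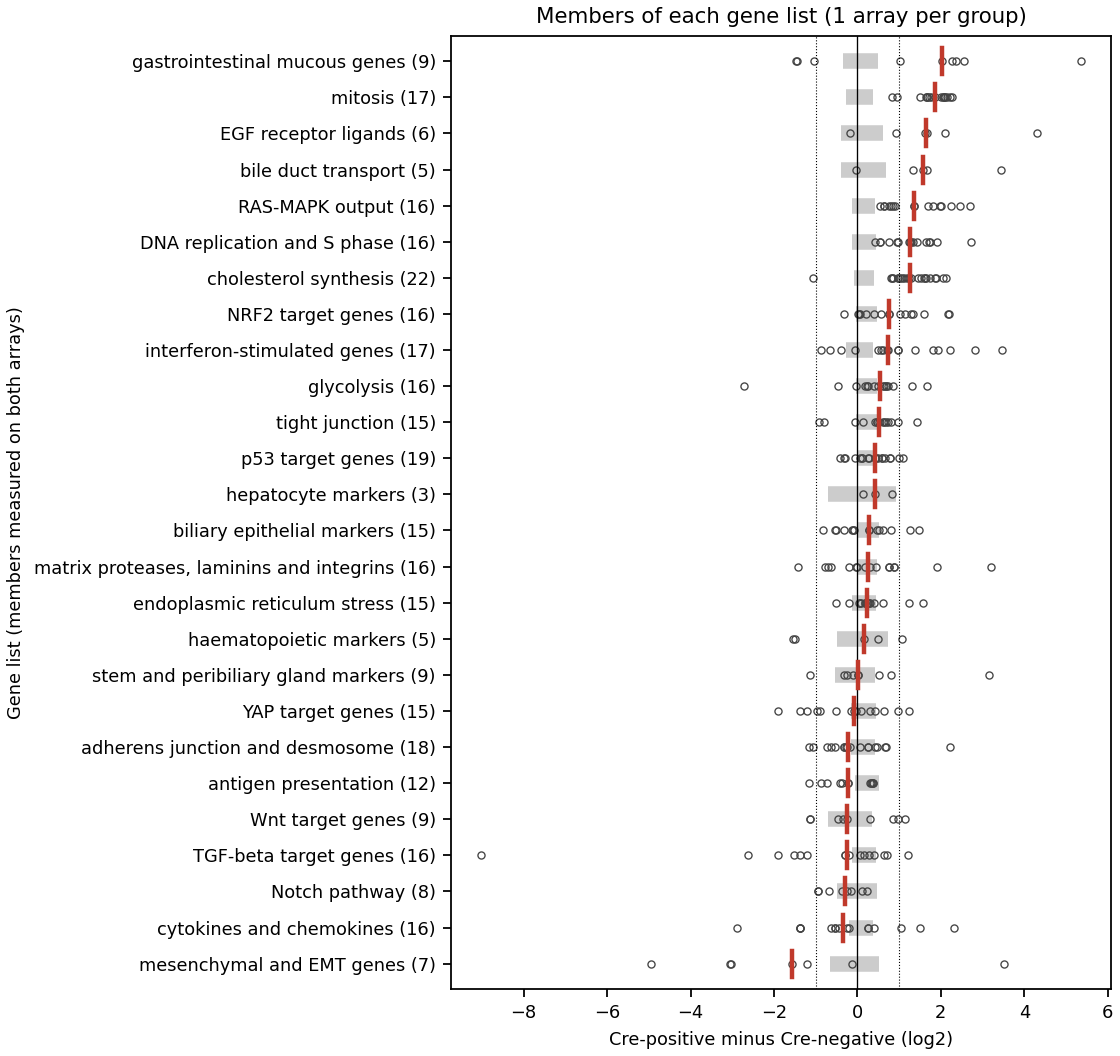
Differences (Cre-positive minus Cre-negative, log2, 1 array per group) of the members of each gene list with at least 3 genes measured on both arrays; circles are genes, red bars the median of the list, and grey bands the central 95% of medians of 10000 random lists matched on mean expression. The medians run from -1.57 for the mesenchymal and EMT genes to 2.03 for the gastrointestinal mucous genes.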

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

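The tests in this part were chosen after the values had been seen. The spike-in transcripts, control RNA added during labelling and not used for the main values, moved against the sample signal. Over 7 spike-in transcripts well above background on both arrays, the unscaled log2 signal in Cre-positive minus Cre-negative was -0.52 on average (SD 0.07), 1.43-fold lower, while the 75th percentile of sample signal was 2.10-fold higher. The gap between them is 1.59 on the log2 scale. Unequal amounts of sample RNA or spike-in in the labelling reactions, and more mRNA per total RNA in the Cre-positive organoid, may each give the gap of 1.59 and cannot be told apart, since each predicts 1 factor for all genes and the amounts used are not given in the sources used here.

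Among 4304 names without an annotated gene that were measured on both arrays, 159 were at least 2-fold higher in Cre-positive than in the control and 492 at least 2-fold lower. Many were dim: 1845 lay at or below the level that bounds the 2445 dimmest annotated genes, and these held 343 of the lower and 42 of the higher names, where the annotated genes had 435 lower and 157 higher. The counts of annotated genes leave these names out, and whether their probes lie within annotated genes was not analysed here.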

How the results depend on the processing

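Loess, spike-in scaling and leaving out Tff1 were chosen after seeing the data; the other settings were not. No paired analysis was possible because each group holds 1 sample, and leaving out a replicate was not possible for the same reason. Spike-in scaling aside, of 1039 recomputed values of probes, lists and named genes, 805 moved by less than the scanner error, 11 that had lain beyond the error changed sign (4 of them with no filter), and 223 moved by more than it. Centring on the median of measured probes moved none beyond the error. Signal over background limits the dim genes. The cause of the shifts below was not tested, except where the setting itself changes which genes enter.

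With 1.5-fold and 3-fold thresholds, 2213 and 367 genes were higher and 1895 and 358 lower. Normexp gave 526 lower genes, all 526 among the 912, and 806 higher, 658 of them among the 910. Quantile normalization gave 857 and 811, of which 779 and 742 were shared. With no filter, 1501 were higher and 7039 lower, and with the stricter filter 402 were lower, the setting itself changing which genes enter. Spike-in scaling gave 10336 higher and 99 lower genes, since it adds the same 1.59 to every gene.

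Under normexp, Cdh1 was -3.80 and Tgfbr2 probe A_51_P450573 0.87; list medians were -0.14 for cytokines, 1.43 for gastrointestinal mucous genes, 0.080 for hepatocyte markers, -1.13 for mesenchymal genes and 1.503 for mitosis. Under quantile normalization, Cdh1 was -4.34 and that Tgfbr2 probe 0.36; medians were 0.51 for NRF2, 1.08 for RAS-MAPK output, -0.33 for YAP, -0.43 for antigen presentation, 1.23 for bile duct transport, 0.0169 for biliary markers, 1.76 for mucous genes, -0.20 for haematopoietic markers, -0.00101 for matrix proteases, laminins and integrins, 0.15 for p53 and 0.26 for tight junctions. In the authors' value table, the same items in that order were -4.40, 0.36, 0.52, 1.08, -0.33, -0.44, 1.25, 0.0186, 1.79, -0.19, 0.00676, 0.15 and 0.27. Under loess on intensity, Cdh1 was -4.34 and that Tgfbr2 probe 0.37; medians were 0.51 for NRF2, 1.103 for RAS-MAPK output, -0.34 for YAP, 1.27 for bile duct transport, 0.00425 for biliary markers, 1.76 for mucous genes, -0.11 for haematopoietic markers and 0.21 for p53, and sign changes gave 0.15 for Wnt targets, -0.00217 for matrix proteases, laminins and integrins and 0.16 for Cel.

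With no filter on dim probes, probes at background on both arrays enter, whose difference the scaling sets near -1.02 (median of 28722 probes), so the values below read background as well as signal. Medians were then 1.27 for EGF receptor ligands, -0.61 for Wnt targets, 0.0253 for bile duct transport, 0.21 for mucous genes, -0.97 for haematopoietic markers, 0.98 for interferon-stimulated genes, -1.03 for mesenchymal genes, -1.02 for hepatocyte markers, and -0.0209 for matrix proteases, laminins and integrins, and the differences of Ctnnd1 and Kdr were -0.0635 and -0.0822. With the stricter filter, medians were 1.86 for EGF receptor ligands, -0.0256 for TGF-beta targets, 2.26 for mucous genes, -0.56 for haematopoietic markers, 1.39 for interferon-stimulated genes and -3.02 for mesenchymal genes, and 0.92 for Wnt targets, a change of sign. On the brightest probe, the hepatocyte median was 0.14, and Apoa2 (-0.27) and Ctnnd1 (-0.0477) changed sign. Without Tff1 the median of the mucous genes was 1.52, which rests on that gene being left out.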

Other observations

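The gene groups in this part were chosen after the data were seen, as were the tests on mesenchymal genes; the tests on the NF-kB and squamous lists were set before those lists were computed, but after the most different genes and the cytokine list, which shares Csf1, had been seen, and 1 condition on the squamous list was added later. A group of acute-phase and innate defence genes, chosen after their values were seen, was low in the Cre-positive organoid. Of 13 measured, 12 were at least 2-fold lower, with a median of -3.44, which follows from that choice. Besides Hp, Acod1 and Nos2 the group held C3, the central complement component (-4.01, from a level of 8.37), Saa1 (-4.09), Chil1 (-4.05), the pattern receptors Nod1 (-3.44) and Tlr2 (-3.22), Lbp (-2.62), Cp (-2.54) and the siderophore-binding protein Lcn2 (-2.51, from 9.31). The exception, Pigr, stood at -0.88. Other pattern receptors were left out: of 7 measured Tlr genes, 2 were at least 2-fold higher, Tlr3 (1.74) and Tlr4 (1.09), and 1, Tlr2, lower. Chil1, like Hp, lay within 1 log2 unit of the lowest level well above background on the Cre-positive array. Of the haematopoietic markers, Itgam (-1.54, from 4.63) and Csf1r (-1.51) were lower too, Cd14 (0.17), Cd3e (0.48) and Cd68 (1.06) were not, Coro1a was seen only on the Cre-positive array, and the other 6, Ptprc and Lyz2 among them, were at background on both arrays. Over quantile, loess, median-centred, value-table and normexp scalings the median ran from -3.49 to -2.39.

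Among 381 families of at least 5 measured genes whose symbols share their leading letters, the Wnt ligands had a median of -1.28 over 9 genes, with Wnt5b at -4.28 and Wnt5a, dim on the Cre-positive array, at -2.47, against Wnt4 at 0.66. The Adamts metalloproteinases stood at -1.47 over 6 genes, with Adamts2 at -3.76. At the other end, the Oas antiviral synthetases had a median of 1.64 over 6 genes, the galectins 1.61 over 7 with Lgals2 at 2.98 and Lgals4 at 2.25 but Lgals1 at -3.16, the carboxylesterases 1.80 over 5, the carbonic anhydrases 1.03 over 8 with Car12, dim on the Cre-negative array, at 2.38, and the aquaporins 1.32 over 5. These 7 were picked from 20 families below and 39 above the central 95% of random lists. Their medians kept their sign under the same 5 scalings, but the Wnt median was -0.61 under loess, and under normexp that of the aquaporins was 0.60 and that of the carboxylesterases 1.19.

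A block of non-coding probes beside Sox4 was low in the Cre-positive organoid. Of 34 probes for reverse-strand transcribed regions on chromosome 13 in mm9 coordinates, 23 were well above background on the Cre-negative array and 12 on both. Of these 12, 9 were at least 2-fold lower, between positions 28551903 and 28952998, and the median of the 12 was -4.04. The other 3 differed by -0.27, 0.31 and -0.15. The 3 probes of Sox4, from 29040826 to 29044541, differed by -0.24, -0.47 and -0.91. In the GRCm38.p6 gene table the long non-coding gene 2610307P16Rik is among the neighbours of Sox4 on one side; whether these probes read it was not analysed here. After loess on intensity the median difference of the genes of each of 20 chromosomes lay between -0.05 and 0.10, against 0.58 for a gain from 2 to 3 copies in every cell.

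Lower mesenchymal and EMT genes (median -1.57 over 7 genes) were weighed against 3 explanations. Fewer fibroblasts in the Cre-positive culture are argued against by the fibroblast markers, of which 1 of 12 (8.33%) was well above background on the Cre-negative array, with the abundant collagens Col1a1 (-3.73), Col1a2 (-4.95) and Col3a1 (-3.92) below the lowest level well above background there (-3.22). That 1 marker, Col6a1, was at least 19.7-fold lower in Cre-positive, the direction that fewer fibroblasts would give. A brightness-dependent difference between the arrays as the whole cause is argued against by loess on intensity, after which the median was -1.40. After normexp background correction the median was -1.13. Loss of TGF-beta signalling, which the KTC alleles as taken here would bring, may contribute and stays open: the TGF-beta target list lay at percentile 0.44 of random lists, but its members went both ways, 9 negative and 7 positive.

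Lower NF-kB output is a candidate explanation for the low acute-phase and innate defence genes. Over 21 measured members of a list of NF-kB targets, the median was -0.28, at percentile 0.02 of random lists, with 18 negative and 3 positive members. Of these, 4 were at least 2-fold lower, Csf1 (-1.38, also in the cytokine list), Vcam1 (-1.36), Icam1 (-1.36) and Birc3 (-1.16), and 0 higher. The median ran from -0.45 to -0.16 over the 5 scalings. Cd40 and Traf1, well above background only on the Cre-negative array, were at least 13.6-fold and 2.60-fold lower. Tnfaip3 and Sod2 differed by -0.16 and -0.03, and the median was less low than that of the acute-phase genes. Of the cytokine list, seen beforehand, the NF-kB list holds Csf1 alone, so its split may partly rest on which targets were listed. Of 16 cytokines measured on both arrays, 3 were at least 2-fold higher, Csf2 (2.32) and Cxcl3 (1.51) among them, and 4 lower. Il1a and Ptgs2, seen only on the Cre-positive array, were at least 7.10-fold and 5.30-fold higher. The explanation stays open.

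The high cornified envelope genes raise the hypothesis of a squamous programme higher as a whole. Without the members that prompted it, the squamous list had a median of 0.67 over 10 genes at percentile 99.7 of random lists, which met the bound set beforehand. A further condition, set after the members were seen, that 0 members be at least 2-fold lower, was not met. Ppl (1.53), Sbsn (1.15), Krt13 (1.14), Krt10 (1.096), Klf4 (0.84) and Evpl (0.51) were positive, while Trp63 (-1.05), Krt14 (-0.90), Tgm3 (-0.76) and Krt5 (-0.33, dim on the Cre-negative array) were negative, and Krt17, seen beforehand, was at -3.63. Scel, Cdsn, Grhl3 and Krt6a, well above background only on the Cre-positive array, were at least 19.8-fold, 6.32-fold, 4.38-fold and 3.88-fold higher. Lor, seen beforehand, was at 3.62. Trp63, Krt14, Tgm3 and Krt17 were lower by more than their scanner errors (0.20, 0.22, 0.20 and 0.23). These values argue against a rise of every member on these arrays. Whether part of the programme was higher stays open.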
